A study of Mus musculus with 6 samples.

How the data were processed

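The series holds 6 Affymetrix arrays of microdissected optic fissure, 3 control and 3 FGFR mutant, grouped by the genotype in the labels. Per the labels, total RNA was extracted with Trizol and biotin-labelled from 10 ug, and MAS5 is the tool named in the submitters' processing notes, with its version and settings not given in the sources used here. The deposited values are linear intensity values, 1 per probe set and array. Their 2% trimmed mean was 150 in every array, so the authors' deposited intensities were already scaled to a common mean and were used as they are, without further normalization. That scaling makes arrays comparable only if most transcripts keep their level, and it does not correct an array in which part of the probe sets lost signal, such as the mutant 8711 array, whose median was 18.1 against 28.6 to 34.5 in the others. Detection calls were not used here.

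The table held 45101 probe sets, of which 64 were manufacturer controls, left out of all gene tests. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and no gene was named from a probe set with several. Gene identifiers matched the reference gene table for 34754, and 0 symbols were updated. Pax2 was not analysed here.

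Intensities were transformed as log2(value + 1.7), the added value being the 10th percentile of all values. Fold changes are on this scale and understate the change of dim genes. Probe sets whose mean log2 value over the 6 arrays was under the 40th percentile (4.07, a linear intensity of 15.1) were left out, leaving 27022, of which 22185 had 1 symbol, for 12282 genes. A gene was represented by its probe set with the highest mean. Of the 60 named genes measured, 30 had more than 1 tested probe set, and in 6 of these (Mitf, Etv5, Cobll1, Lamb1, Pdk1 and Rps24) the probe sets differed in sign. In Mitf, Cobll1 and Lamb1 the differing probe set was lower on the log2 scale only, its linear mean being higher in the mutants. Groups were compared with limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3, with statmod 1.5.0, and Benjamini-Hochberg adjustment with a threshold of 0.05. Intensities are given as mean ± SD of 3 arrays, and log2 differences are mutant minus control. Ratios of 3 prime to 5 prime control probe sets were compared on the log2 scale by exact permutation, two-sided. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

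Gene lists for FGF signalling, eye tissues, neighbouring cell types, cell cycle, signalling pathways and technical effects were fixed before the data were examined. The 24 with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. At that setting 9 lists passed, with an estimated correlation none did, and with fry 2 did, the neural retina progenitor and the FGF-ERK lists. With fry the other lists called by camera had adjusted p from 0.159 to 0.347. The estimated correlation was 0.28 for the pigment epithelium, 0.43 for the mesenchyme and 0.52 for the forebrain list. For the neural retina progenitor and FGF-ERK lists it was -0.0021 and -0.037. Other splits of the same arrays also had lists called at the preset correlation, from 1 to 6. Genes were named by a rule fixed in advance: all Fgfr1 and Fgfr2 probe sets; the 10 largest changes in each direction past the threshold, or, where fewer than 5 passed, the genes with the smallest p up to 5; from each list up to 4 members past the threshold or otherwise the 2 with the smallest p; and Pax2, Mitf, Vax2, Etv5, Spry2 and Dusp6. Crym and Pax6, named because a count of 5 or fewer included them, were chosen after their values were seen. So were Eif2s3y, Dkk3 and Otx1, and, from the FGF-ERK list, Spry4, Flrt3, Fos, Spry1, Spred1, Egr1 and Il17rd. Dct and Pmel, the 2 brightest members of the pigment epithelium list, also lie outside the rule.

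The tests were tried on simulated data with 200 of 27022 probe sets changed. With the spread of all 6 arrays given to each array, limma recovered 1% of 2-fold and 29% of 4-fold changes, with 35 called and 5 of them false, so few single genes can be called at this spread. With 1 array of 3 times the spread, the unweighted fit recovered 0% and 14%, and array weights 14% and 77% with 9 false. In 50 simulations over 12282 genes, a shift of 0.5 in the pigment epithelium list was recovered in 100% at the preset correlation, with 2 false lists in all, and in 56% with an estimated correlation, with 0 false lists. These simulated genes vary independently, unlike real ones.

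Alternatives fixed in advance were other added values, quantile normalization, median centring, other filters, the title number as a block, another variance model, array weights, a threshold of 0.10, other list tests, the mean of all probe sets per gene, the middle control probe set in the RNA ratios, and leaving out each array. Leaving out both 8711 arrays, counting list members without the mutant 8711 array, and Y-linked signal as a covariate were added after seeing the data.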

Results

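Gene expression was measured on Affymetrix arrays in the optic fissure of mouse embryos at E11.5. The optic fissure is the ventral groove of the optic cup, which closes during eye development. Tissue was taken by laser microdissection from C57BL/6J embryos in which the genes of the FGF receptors Fgfr1 and Fgfr2 carried loxP sites on both alleles. In 3 FGFR mutant samples the Six3Cre transgene, which drives recombination in the early eye field, was present, and 3 control samples lacked it. Each sample was 1 array of 45101 probe sets, and the numbers 8711, 9216 and 9266 each named 1 control and 1 mutant array. The labels do not say whether the samples of a group came from separate embryos or pools, so the p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision of every difference below.

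The arrays differed in quality. In the mutant 8711 array the Gapdh control probe sets gave a ratio of 3 prime to 5 prime signal of 93.6, against 4.26 to 15.0 in the other 5 arrays, and its mean correlation with the other arrays was 0.836, against 0.917 to 0.932 for the others. A total of 184 probe sets were bright in the other 5 arrays and dim in this one, and no other array had any such probe set. The Gapdh ratio averaged 9.34 ± 5.13 (SD, n = 3) in the controls and 35.9 ± 50.1 (SD, n = 3) in the mutants, with a two-sided exact permutation p of 0.7. The Actb ratio averaged 8.86 ± 2.94 (SD, n = 3) and 10.9 ± 4.48 (SD, n = 3), with an exact permutation p of 0.8. The smallest p that 3 against 3 arrays allow is 0.1. Ratios of 3 prime to middle signal were also highest in the mutant 8711 array, at 23.6 for Gapdh, against 1.48 to 2.32 in the others, and at 6.51 for Actb, against 3.15 to 4.26.

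**Figure D1:**
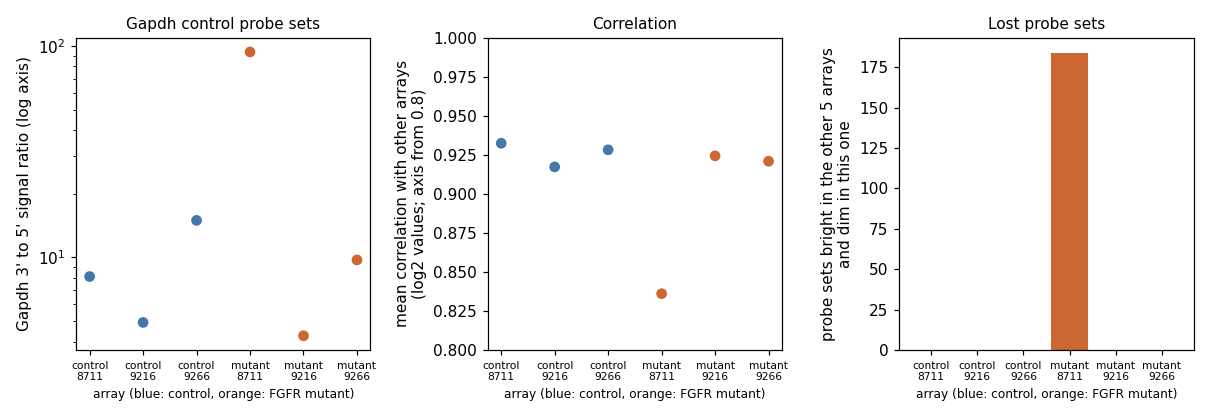
Quality of the 6 arrays. Points show, for each array, the ratio of 3 prime to 5 prime Gapdh signal on a log axis (left) and the mean correlation of its log2 values with those of the other arrays (middle, axis from 0.8), and bars show the number of probe sets bright in the other 5 arrays and dim in that one (right). The mutant 8711 array has a Gapdh ratio of 93.6, a mean correlation of 0.836 and 184 such probe sets, and the other arrays have 0.

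The targeted receptors were read first. The brightest Fgfr2 probe set had intensities of 351, 314 and 474 in control arrays 8711, 9216 and 9266, and of 869.9, 928 and 1316 in the mutant arrays in the same order. The means were 380 ± 83.7 (SD, n = 3) and 1038 ± 243 (SD, n = 3), a log2 difference of 1.44 (SE 0.25), higher in each mutant array than in any control array. The other Fgfr2 probe sets, both dimmer, had log2 differences of 0.99 and 1.32, the last with a control mean of 10.9, under the filter level of 15.1. The brightest Fgfr1 probe set had 247, 89.8 and 238 in the controls and 59.9, 64.1 and 141 in the mutants, with means of 192 ± 88.2 (SD, n = 3) and 88.5 ± 45.9 (SD, n = 3) and a log2 difference of -1.08 (SE 0.52), with overlapping groups. The other Fgfr1 probe sets had -1.46 and -0.59. The first of these had a mutant mean of 11.8, under the filter level, and was -0.61 without mutant 9266, where its value was 1.5. None of these passed adjustment over all probe sets, with an adjusted p of 0.410 for the brightest Fgfr2 and 0.852 for the brightest Fgfr1 probe set. The place of the probes relative to the floxed part of each gene was not analysed here, and a probe outside the deleted part checks nothing, so these values do not check the genotypes in the labels.

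No single probe set passed the test across all 27022 probe sets tested. The 5 genes with the smallest p among those higher in the mutant included Lrrn3, a leucine-rich repeat membrane protein, with 57.9 ± 18.4 (SD, n = 3) in the controls and 448 ± 124 (SD, n = 3) in the mutants, a log2 difference of 2.92 (SE 0.32), and Pcp4, a regulator of calmodulin, with 220 ± 10.9 (SD, n = 3) and 965 ± 280 (SD, n = 3), a difference of 2.08 (SE 0.25). The others, Arap2, Sphkap and Cobll1, had log2 differences of 2.01, 2.54 and 1.48. A second Arap2 probe set had 0.27 and a second Cobll1 probe set -0.54, both dim in mutant 8711 (5.8 and 2.5), and without that array they had 1.27 and 1.24. The 5 lower genes with the smallest p included Ror2, a receptor for Wnt5a, with 263 ± 25.2 (SD, n = 3) and 84.0 ± 7.52 (SD, n = 3), a log2 difference of -1.63 (SE 0.23), and Ccnd2, a cyclin of the G1 phase, with 2790 ± 410 (SD, n = 3) and 1355 ± 86.1 (SD, n = 3), a difference of -1.03 (SE 0.16). The others, Wscd1, Cp, which encodes ceruloplasmin, and Fgf15, had log2 differences of -2.44, -1.82 and -1.74. The adjusted p of each of these 10 genes was 0.356, the smallest of all probe sets. Genes were ranked by their brightest probe set. A dimmer Zic1 probe set, lower in the mutants, had a limma p of 1.38e-04, against 1.82e-04 for Ror2. In limma, 0 probe sets passed an adjusted p of 0.05, while 817 were higher and 689 lower at an unadjusted p under 0.05. The 3 control and 3 mutant values did not overlap for 3640 probe sets (13.5%), against 10% by chance. With array weights, which gave the mutant 8711 array a weight of 0.151, 100 probe sets were higher and 84 lower past the threshold, but that setting called up to 10797 probe sets in other splits of the same arrays, so these calls are not used as findings. Without the mutant 8711 array 1 probe set passed, that of Xist.

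Most genes of the retinal pigment epithelium and of melanin synthesis had higher values in the mutants, and most genes of neural retina progenitors had lower values. Of 22 pigment epithelium genes tested, 19 had higher values in the mutants, with a median log2 difference of 1.0. Rab38, a melanosome GTPase, had 1046 ± 177 (SD, n = 3) in the controls and 2463 ± 211 (SD, n = 3) in the mutants, a log2 difference of 1.25 (SE 0.18). Tfec, a transcription factor of the Mitf family, had 190 ± 26.5 (SD, n = 3) and 479 ± 34.4 (SD, n = 3), a difference of 1.33 (SE 0.21). Mitf itself, which directs pigment cell fate, had 2405 ± 170 (SD, n = 3) and 4582 ± 677 (SD, n = 3), a difference of 0.92 (SE 0.15). A second Mitf probe set, far dimmer, had -0.06 (SE 0.55), with linear means of 149 in the controls and 171 in the mutants. Adjusted over the list alone, 13 of the 22 genes passed, all higher, beside 0 over all genes tested. Without the mutant 8711 array 18 passed, of which only Dkk3 was lower (-1.05). The list differed from other genes by camera with a preset correlation (adjusted p = 1.10e-09), with adjusted p = 0.304 with an estimated correlation (0.339 without mutant 8711). With fry it was not called (adjusted p = 0.159).

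Of 21 neural retina progenitor genes tested, 17 had lower values in the mutants, with a median log2 difference of -0.99. Fgf15, an FGF expressed in retinal progenitors, had 271 ± 49.2 (SD, n = 3) in the controls and 80.0 ± 16.0 (SD, n = 3) in the mutants, a log2 difference of -1.74 (SE 0.27). Six6, a homeobox gene of the optic cup, had 1268 ± 53.1 (SD, n = 3) and 601 ± 149 (SD, n = 3), a difference of -1.11 (SE 0.23). Not all members went the same way: Pax6, a regulator of eye development, had a log2 difference of 0.51 (-0.53 to 0.21 for its dimmer probe sets) and Crym, which encodes mu-crystallin, of 1.72. Adjusted over the list alone, 8 of the 21 passed, 6 lower and these 2 higher, beside 0 over all genes tested. Without mutant 8711, 9 passed, but Pax6 no longer did (adjusted p = 0.0624). Of the 21 genes, 7 are also in other lists, such as Six6 among forebrain markers and Ccnd1 among FGF-ERK targets, so these lists are not independent. The list was lower by camera (adjusted p = 4.13e-07), with adjusted p = 0.0906 with an estimated correlation (0.280 without mutant 8711, where the median was -0.67), and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0235.

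Most feedback and target genes of FGF and ERK signalling had lower values in the mutants. Of 22 tested, 18 had lower values in the mutants, with a median log2 difference of -0.39. Spry2, an inhibitor that FGF signalling induces, had 127 ± 20.3 (SD, n = 3) in the controls and 65.4 ± 16.9 (SD, n = 3) in the mutants, a log2 difference of -0.96 (SE 0.31). Dusp6, a phosphatase of ERK, had 267 ± 51.8 (SD, n = 3) and 141 ± 64.1 (SD, n = 3), a difference of -1.01 (SE 0.40), or -0.61 without mutant 9266. Etv5, an ETS factor downstream of FGF, had a difference of -0.90 (SE 0.42), with control and mutant values that overlapped, and its second, dim probe set had 0.08. Ccnd1, the cyclin D1 gene, had a difference of -1.55 and the transcription factor gene Bhlhe40 of 1.25, in the other direction. Spry4, Flrt3 and Fos were the other higher members, at 0.54, 0.47 and 0.49, and of these Spry4 and Fos were dim. Spry1, Spred1, Egr1 and Il17rd had differences of -0.32, -0.38, -0.26 and -0.40, with overlapping groups. None of the 22 passed adjustment, 0 adjusted over the list alone and 0 over all genes tested, and at an unadjusted p under 0.05 there were 8 lower and 1 higher. Without the mutant 8711 array 9 passed adjusted over the list alone, all lower but Bhlhe40. Dusp6 was among them, while Spry2 (adjusted p = 0.0512) and Etv5 (0.172) were not. The list was lower by camera (adjusted p = 1.93e-04), with adjusted p = 0.128 with an estimated correlation (0.280 without mutant 8711). With fry the adjusted p was 0.0120. In each mutant array the mean of the list lay between -0.41 and -0.47 relative to the control mean, and in the controls between -0.10 and 0.07. Among FGF receptors, ligands and adaptors, Fgf9 had 328 ± 77.9 (SD, n = 3) and 81.4 ± 27.9 (SD, n = 3), a log2 difference of -2.02 (SE 0.34). Adjusted over the list alone, 3 of 20 such genes passed (Fgf9 and Fgf15 lower, Fgfr2 higher), beside 0 over all genes tested and 4 without mutant 8711, and the list as a whole was not called (camera adjusted p = 0.717).

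**Figure D2:**
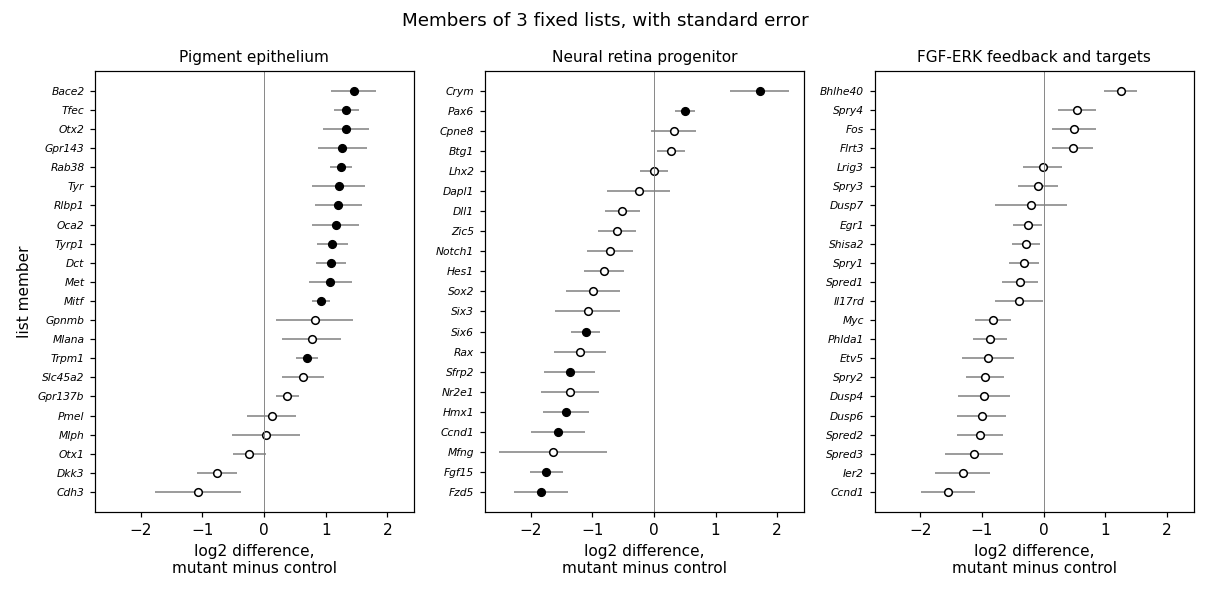
Log2 difference (mutant minus control, horizontal axis) of each tested member of the pigment epithelium, neural retina progenitor and FGF-ERK lists (vertical axis), with its standard error as a bar. Filled points passed when adjusted over the list alone, 13 of 22, 8 of 21 and 0 of 22, and open points did not.

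Cell cycle genes were lower by a small amount, with 31 of 33 below the controls and a median log2 difference of -0.32. Tk1, the thymidine kinase of DNA synthesis, had a difference of -0.96 (SE 0.26), and the mitotic kinase gene Aurka of -0.56 (SE 0.23). No member passed, 0 adjusted over the list alone and 0 over all genes tested. The list was lower by camera (adjusted p = 6.47e-06), with adjusted p = 0.281 with an estimated correlation. Without mutant 9266 the median was -0.19 and the camera adjusted p 0.0312. Neurogenic and retinal ganglion cell genes had a median of -0.34 over 18 genes. Onecut2, a transcription factor of early retinal neurons, had 128 ± 14.5 (SD, n = 3) and 31.4 ± 13.3 (SD, n = 3), a difference of -2.06 (SE 0.40), and was the 1 member that passed adjusted over the list alone, beside 0 over all genes tested. Atoh7, which specifies ganglion cells, had a difference of -2.51 (SE 0.99), with 1 bright control array (293 in control 9266, against 48.7 and 16.5 in controls 8711 and 9216), and a mutant mean of 10.3, under the filter level of 15.1, and it was -1.42 without that array. The list was lower by camera (adjusted p = 0.00559), with adjusted p = 0.575 with an estimated correlation. Its adjusted p was 0.0513 without control 9266 and 0.0767 without mutant 9266, where the call was lost, and with 1 array left out its median ran from -0.57 (control 9216) to -0.09 (control 9266). Forebrain and diencephalon markers had a median of -0.56 over 9 genes, led by Six6 and by Fezf2 (-1.16, SE 0.37), with 1 member adjusted over the list alone and 0 over all genes tested. Of the 9, 4 are also in other lists. The camera adjusted p was 0.00559, with adjusted p = 0.575 with an estimated correlation. Its adjusted p was 0.0780 without control 9216 and 0.0907 without mutant 8711, where the call was lost, and its median was -0.31 and -0.08 there, and -0.88 without control 8711.

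Genes of the optic stalk, optic disc and ventral optic cup went both ways. Of 27 tested, 18 were lower, with a median log2 difference of -0.16. At an unadjusted p under 0.05, 6 were lower and 2 higher. Zic1, a zinc finger factor, had 4495 ± 684 (SD, n = 3) in the controls and 2066 ± 757 (SD, n = 3) in the mutants, a log2 difference of -1.19 (SE 0.31), and Gas1, a cell surface protein that binds hedgehog ligands, had 1310 ± 443 (SD, n = 3) and 2902 ± 685 (SD, n = 3), a difference of 1.17 (SE 0.28). A second Zic1 probe set, with means of 3134 in the controls and 1027 in the mutants, had -1.64 (SE 0.22). Dimmer Gas1 probe sets had 0.14 and 0.58. Vax2, a homeobox gene of the ventral optic cup, had a difference of -0.35 (SE 0.30) with overlapping groups, from -0.58 to -0.13 with 1 array left out. Pax2 was not analysed here. No member passed, 0 adjusted over the list alone and 0 over all genes tested. The camera adjusted p was 0.0470, close to the threshold, with adjusted p = 0.321 with an estimated correlation. The call was lost, at 0.0513 to 0.0797, when any array but mutant 8711 was left out. The median was -0.43 without control 9216 and -0.30 without mutant 9266. Without mutant 8711 the adjusted p was 0.0359, or 0.367 with an estimated correlation. There 10 members passed adjusted over the list alone, most of them lower and some, such as Gas1, higher.

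Most periocular mesenchyme and macrophage markers were higher in the mutants. Of 29 periocular mesenchyme markers, 27 had higher values, with a median log2 difference of 0.58. Prrx1, a homeobox gene of mesenchyme, had 126 ± 38.3 (SD, n = 3) and 246 ± 12.5 (SD, n = 3), a difference of 1.0 (SE 0.28), and Twist1, at low intensity, had 13.5 ± 5.89 (SD, n = 3) and 46.3 ± 8.0 (SD, n = 3), a difference of 1.73 (SE 0.42). The list was higher by camera (adjusted p = 5.38e-05), with adjusted p = 0.575 with an estimated correlation. Of 23 macrophage markers, 18 had higher values, with a median of 0.26. Lyz1, a lysozyme, had a difference of 1.19 (SE 0.42) with overlapping groups, and Csf1r, the receptor of colony stimulating factor, of 0.49 (SE 0.19). The macrophage list was called by camera (adjusted p = 0.00795), with adjusted p = 0.575 with an estimated correlation. No member of either list passed, 0 adjusted over the list alone and 0 over all genes tested. Control 9216 was the lowest array for both lists, at -0.56 and -0.46 relative to the control mean, and without it the mesenchyme median was 0.19 (adjusted p = 0.0374) and the macrophage median 0.17 (adjusted p = 0.226). The mesenchyme values overlapped between the groups, with mutant 8711 at 0.32 and control 9266 at 0.35. Without mutant 9216 the macrophage adjusted p was 0.0648, so leaving out either 9216 array ended that call. Without mutant 8711, 3 mesenchyme markers passed adjusted over the list alone.

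**Figure D3:**
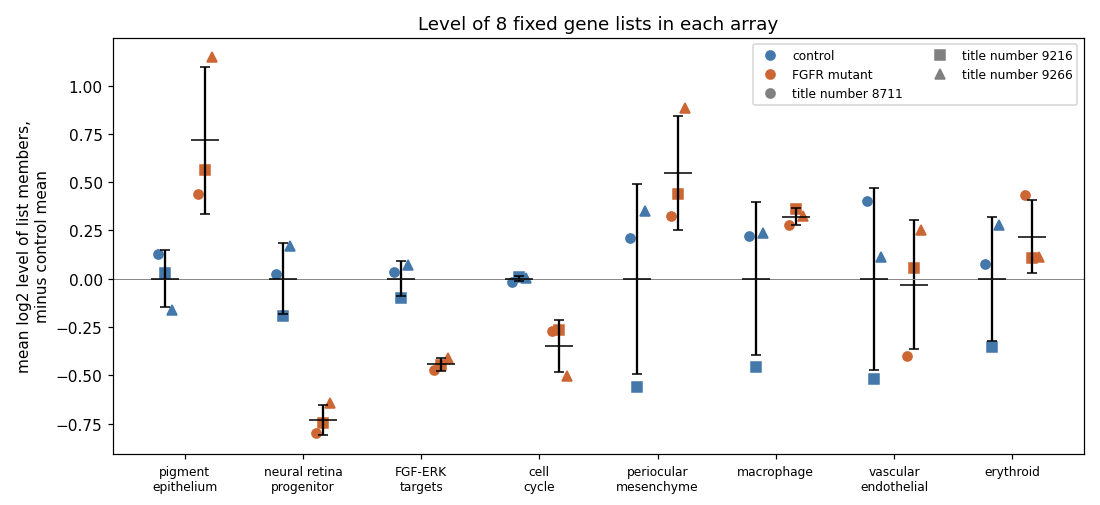
Mean log2 level of the members of 8 gene lists in each array, relative to the control mean (vertical axis), with controls in blue, mutants in orange and 1 symbol per title number. Black marks are the group mean and SD of 3 arrays. The mutant arrays lie between 0.44 and 1.15 for the pigment epithelium list and between -0.80 and -0.64 for the neural retina progenitor list, outside the range of the control arrays.

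The other 15 lists tested, the FGF receptor list above among them, were not called. Vascular endothelial markers (camera adjusted p = 0.895), with Eng at a log2 difference of -0.99 and Kdr at -0.95, erythroid markers (0.185), with Hbb-bh1 at 0.48 and Klf1 at 0.36, lens markers (0.0846), with Cryaa at -1.73 and Maf at -0.45, and neural crest, glial and melanoblast markers (0.766), with Zeb2 at -0.54 and Fabp7 at 0.51, had 0 members passing adjusted over the list alone and 0 over all genes tested. For surface epithelium markers (0.118), 1 of 11 passed adjusted over the list alone, beside 0 over all genes tested: Dsp, a desmosome gene, at 1.40 but with a control mean of 11.2, under the filter level of 15.1, while Krt18 had 1.47. Without mutant 8711, 0 of the 11 passed. Among retinoic acid pathway genes (0.0611), 2 of 18 passed adjusted over the list alone, beside 0 over all genes tested: Rxrg, a retinoid X receptor, at 1.98, and Rbp4, which carries retinol, at 1.99. Without mutant 8711, 5 passed. Among Hedgehog pathway genes (0.895), 2 of 14 passed adjusted over the list alone, Ccnd2 and Gas1, beside 0 over all genes tested. No member passed in the Wnt list (0.824), where Tnfrsf19 had 1.44 and Fzd5, a Wnt receptor of the retina, had -1.83, in the BMP and TGF-beta list (0.717), where Bmp2 had 1.64 and Bmpr1b had -1.08, in the basement membrane and adhesion list (0.936), where Lamb1, a laminin chain, had 0.82 (-0.38 for its dimmest probe set) and Itgb8 had -0.98, in the p53 and cell death list (0.895), where Gtse1 had -0.81 and Trp53inp1 had 0.63, in the dissection stress list (0.993), where Dusp1 had -0.97 and Ier2 had -1.32, in the hypoxia and glycolysis list (0.717), where Pdk1 had 1.02 (-0.32 for its dimmest) and Slc2a3 had 1.08, or in the ribosomal protein list (0.824), where Rps24 had 0.20 (-0.14 for its dimmest) and Rpl37 had 0.54. For 12 of the genes just named, leaving out 1 array divided the difference by more than 1.5. Without mutant 8711, Eng had -0.56, Kdr -0.45, Klf1 0.19, Gtse1 -0.49, Ier2 -0.85 and Rpl37 0.14. Without control 9216, Hbb-bh1 had 0.30, Maf -0.24 and Fabp7 0.14. Without mutant 9216, Cryaa had -1.10 and Trp53inp1 0.42, and without mutant 9266 Zeb2 had -0.23. Without mutant 8711, 7 members of the Wnt list, Tnfrsf19 and Fzd5 among them, and 1 of the BMP list, Bmpr1b, passed adjusted over the list alone. The sex-linked list held 4 tested genes, under the minimum of 5, and was not tested as a list. The median and the test differed in sign for the vascular endothelial and p53 lists (medians of 0.07 and 0.12, means of -0.03 and -0.05, both lower by camera) and for the dissection stress list (0.10, mean 0.04), and the mean differed from both for the basement membrane list (0.02, median -0.02). Leaving out 1 array brought some of these lists past the threshold at the preset correlation: lens without mutant 9266 (8.80e-04) or control 8711 (0.0171), erythroid without control 9266 (0.0186), surface epithelium without mutant 9216 (0.0160), and retinoic acid without control 8711 (0.0232), control 9266 (0.0493) or mutant 8711 (0.0372, but 0.367 with an estimated correlation).

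Sex-linked genes differed between the arrays of each group. Xist, the RNA of the inactive X chromosome, had intensities for its brightest probe set of 1270, 4313 and 2792 in control arrays 8711, 9216 and 9266 and of 2950, 19.5 and 20.4 in the mutant arrays in the same order. Eif2s3y, a Y-linked gene, had 698, 1.3 and 535 in the controls and 4.2, 1301 and 1144 in the mutants. A second Xist probe set disagreed with it in mutant 8711, with 12.9 there, against 0.7 in mutant 9216 and 2.7 in mutant 9266. The dimmest Xist probe set had 45.0, 4.0 and 1.6 in these arrays. In the controls, in the order above, the second had 519, 5733 and 530.2, and the dimmest 38.4, 565 and 99.2. The log2 difference of the brightest Xist probe set was -4.48 (SE 1.88) with an adjusted p of 0.852, and without the mutant 8711 array it was -6.84 with an adjusted p of 0.0163. The others had -7.77 (SE 1.09) and -3.78 (SE 1.28), with adjusted p of 0.356 and 0.806. Uty, also Y-linked, had a difference of 0.88 (SE 1.57).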

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

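The tests of whole transcript levels, of the pigment epithelium list without the mutant 8711 array and of embryo sex from Xist and Eif2s3y were chosen after the result was seen, and the Y-linked covariate was added after the data were seen.

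The control probe sets of Gapdh, which no comparison of gene levels uses, gave a 3 prime to 5 prime ratio of 93.6 in the mutant 8711 array, above the highest control array, at 15.0. The ratios of 3 prime to middle signal were highest there too, at 23.6 for Gapdh (1.48 to 2.32 in the others) and 6.51 for Actb (3.15 to 4.26), and so was the Actb 3 prime to 5 prime ratio, at 14.8 (6.03 to 12.1), which go with shortened cDNA but are of the genes that prompted it. A change in the level of whole transcripts would dim every probe set of a gene, yet 76.6% of the genes with a lost probe set (98 of 128, or 98 of the 106 that had another bright one) kept another bright probe set within 1 log2 unit. Scaling does not account for most of the losses, since 57.6% of the 184 were still lost after quantile normalization. Shortened cDNA in this array may explain it and stays open: of the transferrin receptor and pyruvate carboxylase controls, chosen beforehand, 0 of 2 had their highest ratio in this array (2.30, within the other arrays' range, and 1.91, below it), which goes against it, but both 5 prime signals (6.0 and 12.7) lay under the filter level of 15.1, too dim for the ratio to decide.

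The pigment epithelium genes were higher and the neural retina genes lower in the mutants, with 27 of 29 mesenchyme and 18 of 23 macrophage markers also higher, which could be a change of cell fate or of the tissue dissected. The mutant 8711 array does not account for it, since without that array the median of the pigment epithelium list was 1.02 and that of the neural retina list -0.67, against -0.99 with all arrays, and both were called at the preset correlation, though not at an estimated one (adjusted p = 0.339 and 0.280). A lower share of neural retina, raising all other cell types alike, cannot be told apart from a specific rise: the pigment epithelium list exceeded the vascular endothelial list by 0.75 log2 more in the mutants, 2.04 times the pooled SD, but mutant 9216 (0.51) lay below control 9216 (0.55). More pigment epithelium in the microdissected tissue also stays open. Of the 10 brightest list members, 4 lay more than 2 SE below the list median, where 5 would have counted against it. Of the 22 tested genes, 1 is in another list. Among the 10 brightest, 8 were higher, with Dct at 3147 and 6647 and Pmel at 4119 and 4899 in controls and mutants. Dkk3 (962 and 584) and Otx1 (1206 and 1034) were lower. The log2 difference of Pmel was 0.59 without mutant 8711 (2320), against 0.12 with it. Embryo sex as a covariate left the median at 0.997, but 2 of 3 arrays in each group carried Y-linked signal. That balance of the groups fixes the outcome, so the test is void. Only the presence of Y-linked signal was balanced. The 2 controls that carried it had 1270 and 2792 for the brightest Xist probe set, against 19.5 and 20.4 in the 2 mutants. Sex may therefore still differ between the groups, which was not tested.

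Xist and Eif2s3y differed between arrays of one group. One explanation, embryo sex, with pools of both sexes in 2 control arrays, could account for it but stays open: by the brightest Xist probe set both signals exceeded 100 in 2 arrays, control 8711 and control 9266, and each array with Xist under 100 had Eif2s3y over 100. The other Xist probe sets were under 100 in mutant 8711 (12.9 and 45.0), where Eif2s3y was 4.2. The 12.9 goes against this explanation unless that probe set lost signal in that array, which was not tested. The 45.0, of the dimmest probe set, lay above its 38.4 in control 8711, so the cut at 100 decides nothing there. By this dimmest probe set no array had both signals over 100, the outcome set to count against this explanation. Its values in controls 8711 and 9266 (38.4 and 99.2) still lay between 565 in control 9216 and 4.0 and 1.6 in mutants 9216 and 9266. For this probe set the cut at 100 therefore decides nothing about pools of both sexes. The labels used here give neither the sex nor the number of embryos per sample, so this is a hypothesis. No biological explanation from the genotype was tested, and Xist was low in 2 or in 3 mutant arrays, depending on the probe set.

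With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Without weights, the real split gave 0 probe sets and the highest other split 0, so 10 of 10 were as large. With array weights the real split gave 184 and the highest other 10797 (control 8711, control 9266 and mutant 8711 against the rest), another gave 6108, and 3 of 10 were as large. The weights were estimated anew in each split. The cause of counts so far above the real one was not tested, and the fit without weights cannot show it, since it gave 0 in every split, the real one included. For gene lists the real split gave 9 and the highest other 6, and 1 of 10 was as large. Every other split also called lists at the preset correlation, from 1 to 6, so such calls also arise between mixed groups.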

How the results depend on the processing

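Leaving out both 8711 arrays, list members counted without mutant 8711 and the Y-linked covariate were tests chosen after seeing the data.

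Over 1073 combinations of a named gene and a setting, 1047 kept their direction and side of the threshold, 24 passed it anew and 2, both for Uty, changed sign. Of 477 for lists, 381 kept both, 37 lost a call, 15 gained one, 1 turned with a call and 43, over 11 lists, turned without one. No probe set passed in limma with other added values, scalings, filters, variance models or a threshold of 0.10, with the smallest adjusted p between 0.238 and 0.511. At an unadjusted p under 0.05, counts ran from 692 without control 8711 to 4596 with array weights, against 1506. Median centring moved the median of all tested probe sets from -0.05 to 0.06. With array weights 184 probe sets and 120 genes passed, Fgfr2 had a log2 difference of 1.47 and 5 lists passed. With an estimated correlation 0 lists passed and with fry 2, against 9. Leaving out 1 array gave 0 to 1 probe sets and 0 to 1 genes, and leaving out both 8711 arrays gave 1 probe set, of 1 gene, Xist. Called lists lost their call with array weights (macrophage 0.107, neurogenic 0.203, forebrain 0.295) and without a filter (forebrain 0.146), and the optic stalk list in both and in most other settings with the preset correlation (0.0506 to 0.0987). Without mutant 8711 the log2 ratio difference turned, and over all arrays left out in turn it ran from -0.012 to 0.64 for Actb and from -0.39 to 1.84 for Gapdh. Lists that passed anew with all 6 arrays, at the preset correlation, were surface epithelium with an added value of 1 (0.0424) or the mean of probe sets (0.0274), erythroid with the mean of probe sets (0.0391), lens with median centring (0.0250), and retinoic acid with median centring (0.0129) or the Y-linked covariate (0.0383). Without both 8711 arrays, lens (0.0237) and retinoic acid (0.0166) passed. The cause of these changes was not tested. Dim signal limits what the arrays can show, and the filter level was 15.1.

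The title number as a replicate block gave 0 probe sets and 8 lists, with the optic stalk list at 0.0566, and a random block gave 0 probe sets. The lists were not run with a random block, since camera takes none. Same-number arrays deviated together only for 9216 (correlation 0.48, against 0.05 for 8711 and -0.11 for 9266), and not every array correlated best with its own number. The mutant deviations were taken from a mean that includes the mutant 8711 array, so these correlations cannot decide whether the numbers pair the arrays.

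These adjusted p belong to lists whose direction turned, uncalled unless said. With quantile normalization: vascular endothelial 0.871, dissection stress 0.871, ribosomal 0.691. With median centring: basement membrane 0.896, dissection stress 0.896. Without a filter: FGF receptors 0.968, p53 0.985. With the 60th percentile filter: FGF receptors 0.884, basement membrane 0.983. With array weights: p53 0.529, dissection stress 0.604, hypoxia 0.988, ribosomal 0.988. With fry: p53 0.997, Wnt 0.997, basement membrane 0.966, dissection stress 0.966. With the mean of probe sets: vascular endothelial 0.914, dissection stress 0.888. Without both 8711 arrays: vascular endothelial 0.0193 (called, higher), basement membrane 0.710, dissection stress 0.820, ribosomal 0.291. With the Y-linked covariate: basement membrane 0.978. Leaving out each array in turn, adjusted p ran from 0.122 to 0.948 for vascular endothelial, 8.80e-04 (called) to 0.908 for lens, 0.356 to 0.961 for neural crest, 0.437 to 0.981 for p53, and 0.656 to 0.948 for basement membrane and Hedgehog genes, 0.672 to 0.969 for dissection stress, 0.38 to 0.948 for hypoxia and 0.142 to 0.961 for ribosomal genes. Uty ran from -0.41 to 2.40 (log2).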

Other observations

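The genes in this part were chosen after their values were seen, and no test beyond the comparison above was run on them.

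The genes named here lie outside the fixed lists, had a small unadjusted p and did not overlap between the groups, and they stand for no tested theme. Rspo2 and Rspo3, which encode R-spondins, enhancers of Wnt signalling, were higher, with log2 differences of 2.50 (SE 0.34) and 1.69 (SE 0.28). Reln, which encodes reelin, had 459 ± 54.0 (SD, n = 3) in the controls and 1996 ± 686 (SD, n = 3) in the mutants, a difference of 2.06 (SE 0.29), and Robo1, a receptor for Slit proteins, had 1.36 (SE 0.20). Pdgfc, a platelet-derived growth factor, had 1.33 (SE 0.20), and Sgk1, a kinase, had 1235 ± 359 (SD, n = 3) and 4154 ± 728 (SD, n = 3), a difference of 1.77 (SE 0.24). Lower in the mutants were Uhrf1, which maintains DNA methylation at replication, at -1.61 (SE 0.29), Nrarp, a target of Notch signalling, at -1.22 (SE 0.23), and the neurotrophin receptor gene Ntrk2 at -1.35 (SE 0.28). None passed adjustment over all probe sets in limma, with adjusted p from 0.356 to 0.50.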
